A study of Danio rerio with 10 samples.

How the data were processed

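The deposited files hold 1 library each. The 6 whole-embryo libraries were strand-specific (dUTP method) from Trizol-extracted RNA, and the 4 fraction libraries were unstranded from RNA separated with the PARIS kit, all of polyadenylated RNA, per the labels' protocols. Reads were aligned with TopHat2 2.0.8 and the genome build was danRer7, per the submitters' processing notes. The counting tool is not given in the sources used here. Per the file headers, each file lists 15865 RefSeq transcript records with position, length, a read count and RPKM. The deposited counts are whole numbers and not normalized. The authors' RPKM equals the count divided by the transcript length in kilobases and by 1 total per file scaled to 1e+06 reads, to within a relative 8.22e-15; that total exceeds the sum of the listed reads, and reads outside the listed transcripts were not analysed here. Replicate 1 files of the whole embryos use another header and another start coordinate convention than the other files, so that replicate number coincides with a difference in the authors' processing. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be mixed.

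Groups were taken from the labels' titles and genotypes: 3 whole-embryo groups of 2 libraries and 4 fraction groups of 1. The listed reads ranged from 34060890 to 82752349 in whole embryos and from 7164408 to 19195327 in the fractions. For each of 14563 gene symbols the record with most reads over all libraries was kept, and genes with a mean RPKM of 1 or more over the 6 libraries were tested (10147). Of these, 370 have several placements, and their reads may be divided between copies. Of all symbols, 13871 had an accession in the supplied RefSeq gene table, which was used for current names only.

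The plan fixed before the data were examined assumed limma on log2(RPKM + 1), or edgeR's quasi-likelihood test if counts were present, in 1 model of all 6 libraries without a replicate term. Counts were present, so edgeR 4.0.16 (R 4.3.3, glmQLFit and glmQLFTest) is the test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. TMM scaling in place of values as deposited, and 1 record per gene, were chosen after the files were seen and before any fit. The fit with replicate number as a block was set down beforehand as a second fit. That its values lead the report was decided after the fit without it had called no gene, on the ground that the files mark replicate number as a processing batch. With 2 libraries per group and 3 groups it leaves 2 residual degrees of freedom, against 3 without the block. Standard errors of fold changes were obtained from the fold change and the F statistic.

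The rule for named genes took, among genes past the threshold with both libraries of a group outside the range of the other and a mean RPKM of 5 or more in the higher group, the 10 largest rises and falls, without placeholder names; where fewer than 5 passed, it took the 5 smallest p-values per direction. It also took up to 4 members per gene list, and for the fractions the 10 largest and smallest differences. The same rule was applied to the fit with the block after that fit was seen. Members named because they passed in the fit with the block, and snrnp200, prpf8 and eftud2, lie outside the fixed rule. Not every gene taken by the rule is printed, and which ones are was settled after their values were seen. A fixed set of 31 gene lists was tested, of which 30 had at least 3 tested members and the mitochondrially encoded list had none in the files. Results for 1 gene and 1 of the lists are not reported here, though the counts of lists include it. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry, which does not set a list against the other genes. With an estimated correlation camera uses the residual degrees of freedom of the fit, 3 without the block and 2 with it. Few lists can pass it then, whatever their correlation, so a call lost under it need not come from correlated genes. For the fractions, log2((nucleus + 1)/(cytoplasm + 1)) of RPKM was computed for 8631 genes, and list medians were placed among 10000 random lists matched on expression.

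The scripts were tested on simulated counts for the 10147 genes with 200 genes changed. Without the block, 0% of genes changed 2-fold or 4-fold between mutants and siblings were recovered, with 0 false calls. With the block 46% and 98% were recovered, with 19 false calls, more than a rate of 5% allows; for mutants against wild-type controls the shares were 45% and 96%, with 21 false calls. Alternatives were other pseudocounts, filters, scalings and moderation, limma, DESeq2 1.42.0, all records, leaving out each library, and fits with only the libraries compared. DESeq2, the authors' totals, all records and the block in combination with other alternatives were added after the data were seen.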

Results

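The series measured polyadenylated RNA of zebrafish embryos (Danio rerio, TL strain) at 36 hours post fertilization (hpf) in 10 libraries. The 6 whole-embryo libraries fell into 3 groups of 2, each library made from 30 embryos: wild-type controls from crosses of TL fish, and siblings and homozygous fn10a mutants from crosses of fn10a heterozygotes. Siblings pooled heterozygous and wild-type embryos. The other 4 libraries were nuclear and cytoplasmic RNA of siblings and of mutants, with 1 library per fraction and genotype. The reads on listed RefSeq transcripts numbered 73755759 and 36527992 in the wild-type controls, 82752349 and 34620508 in the siblings and 79226574 and 34060890 in the mutants, replicates 1 and 2 in that order. They numbered 14141991 in sibling nuclei, 17696776 in sibling cytoplasm, 7164408 in mutant nuclei and 19195327 in mutant cytoplasm. Nothing in the labels says whether replicates came from separate clutches, so p-values measure the spread between these libraries, which may be technical.

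Replicate number separated the whole-embryo libraries more than genotype did. The principal component with the most variance (60.1%) parted replicate 1 from replicate 2 in all 3 groups, and the next (21.5%) parted the mutants from the other 2 groups. The share of the authors' read total on listed transcripts was 54.2% to 58.8% in replicate 1 and 31.6% to 33.7% in replicate 2, and the files of the 2 replicate numbers were written in different formats. Replicate number was therefore treated as a processing batch. Values below come from the fit with a term for it, and "rose" and "fell" are kept for genes past an adjusted p of 0.05 in that fit. The design fixed before the data were examined had no such term, and its counts stand beside each comparison. Because replicate 2 was lower or higher than replicate 1 for many genes in every group, the SDs of RPKM given below hold this batch difference, which the standard errors of the fold changes do not.

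**Figure D1:**
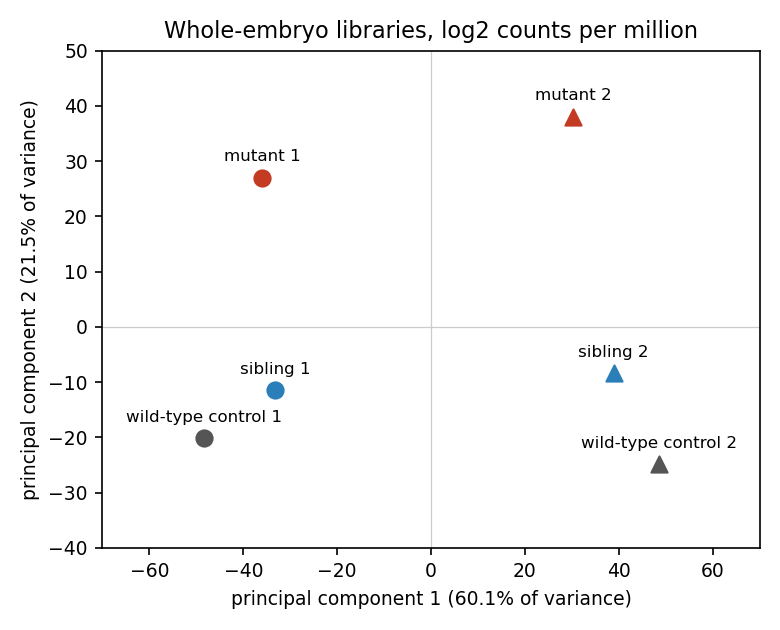
Principal components of log2 CPM (read counts scaled to the library size) in the 6 whole-embryo libraries, component 1 (60.1% of variance) on the x axis and component 2 (21.5%) on the y axis; circles are replicate 1 and triangles replicate 2. Component 1 parts the replicate numbers and component 2 the mutants from the siblings and wild-type controls.

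The labels name the allele fn10a and no gene. From knowledge of the study, and not from the labels, fn10a is a mutation of eftud2, which encodes a GTPase of the U5 small nuclear ribonucleoprotein, a core part of the spliceosome. It was singled out after its values had been seen. The eftud2 transcript (NM_200508, danRer7 chromosome 3, 16009001 to 16033616, minus strand) stood at 30.2 and 10.5 RPKM in the wild-type controls, 28.1 and 9.91 in the siblings and 11.3 and 3.60 in the mutants. It fell in mutants against siblings (log2 fold change -1.35, SE 0.131, adjusted p = 0.0183 by edgeR's quasi-likelihood test), by -1.19 in replicate 1 and -1.51 in replicate 2. Against wild-type controls it fell by 1.49 (adjusted p = 0.0113). In the fraction libraries it stood at 16.5 RPKM in sibling nuclei and 6.83 in mutant nuclei, and at 18.9 in sibling and 7.21 in mutant cytoplasm. These are values as deposited, by which the median gene changed by a log2 of -0.837 in mutant nuclei and 0.0203 in mutant cytoplasm. Much of the nuclear difference of eftud2 was thus shared by most genes. Siblings and wild-type controls did not differ detectably (log2 -0.14, SE 0.128, adjusted p = 0.73). The transcript was thus lower in every library labelled mutant than in the library of its own replicate or fraction from the other groups.

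The comparison of mutants with their siblings asks which transcripts differ when embryos of the same crosses lack a functional fn10a locus. mdm2, which encodes a ubiquitin ligase, rose from 9.88 ± 3.81 to 55.6 ± 23.8 RPKM (log2 2.51, SE 0.148, adjusted p = 0.0122). The proapoptotic gene bbc3 (puma) went from 0.183 to 5.31 RPKM (log2 5.01, SE 0.488). The initiator caspase gene casp8 rose 7.40-fold, gadd45aa 8.49-fold, phlda3 7.13-fold and ccng1, a cyclin gene, 3.39-fold.

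The list of pre-mRNA splicing genes was higher by camera with the preset correlation. Of 58 tested members 21 rose and 1, eftud2, fell, 36 did not pass, and the median fold was 1.56. Adjusted over the list alone, 34 were higher and 3 lower. The U4/U6 and tri-snRNP genes prpf3 and prpf31 rose most among the members named by rule: prpf3 from 13.4 ± 6.57 to 66.7 ± 26.8 RPKM (SD, n = 2; log2 2.39, SE 0.135, adjusted p = 0.0122) and prpf31 from 17.4 ± 6.63 to 79.8 ± 20.5 RPKM (log2 2.27, SE 0.133). prpf3 has 2 records at 2 places in the files, so its reads may be divided between copies. snrpd3, a core Sm protein gene, rose 3.39-fold and sart1, of the tri-snRNP, 3.29-fold. The genes for the U5 partners of the eftud2 protein, snrnp200 (a helicase) and prpf8, which were picked after their values had been seen, rose 3.32-fold and 2.41-fold. The list's adjusted p was 1.72e-18 by camera, 0.0397 with an estimated correlation, and 0.502 with an estimated correlation and the replicate term. Without the term the estimated correlation was 0.00886, below the preset 0.01, so a higher correlation does not explain the rise from 1.72e-18 to 0.0397. With the term it was 0.0921. By fry the adjusted p was 0.0123 without the term and 0.0488 with it. The list kept an adjusted p under 0.05 and an upward direction with the preset correlation in all 19 settings tried with the replicate term and all 19 without it.

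**Figure D2:**
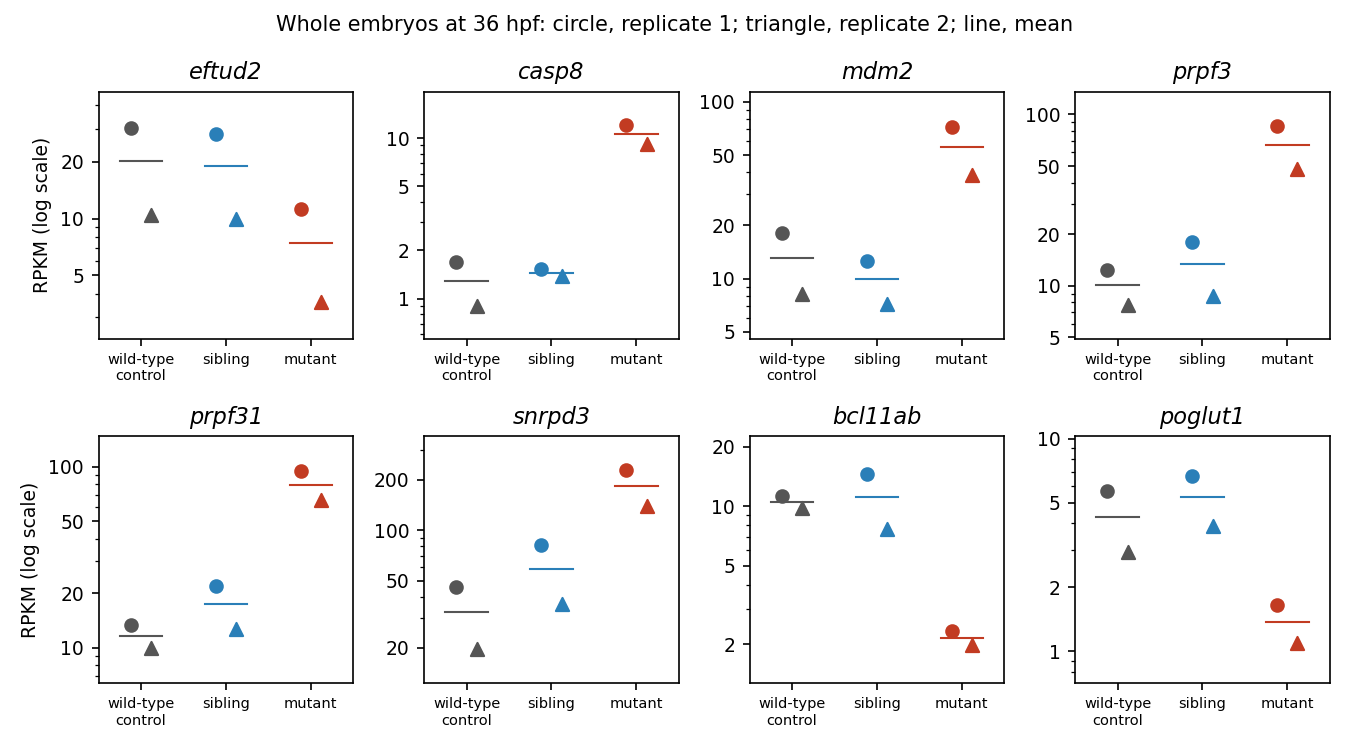
RPKM on a log axis of 8 genes in the 6 whole-embryo libraries; circles are replicate 1, triangles replicate 2 and horizontal lines the group mean. Both mutant values lie below both sibling values of bcl11ab and poglut1 and above them for mdm2, casp8, prpf3, prpf31 and snrpd3; for eftud2 the mutant value of replicate 1 (11.3) lies above the sibling value of replicate 2 (9.91), and mutants are lower within each replicate number.

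Other genes with the largest rises were chosen by the rule for named genes applied to the fit with the replicate term. brf2, a subunit of the RNA polymerase III initiation factor of U6 snRNA genes, rose 7.24-fold (2.12 ± 1.17 to 14.2 ± 5.30 RPKM, SD, n = 2). kiaa0947l rose 6.90-fold, bmb 8.55-fold and lnx1, which encodes a ubiquitin ligase, 5.93-fold. fos, an immediate early transcription factor gene, rose 15.3-fold against siblings, from 1.17 to 17.8 RPKM, and stood at 13.3 RPKM in wild-type controls. The largest falls included ankrd1b (log2 -2.61, SE 0.249), the zinc finger transcription factor genes bcl11ab (log2 -2.27, SE 0.196, 11.1 ± 4.87 RPKM in siblings and 2.16 ± 0.260 in mutants) and bcl11aa (log2 -1.45), lrrn1 (log2 -1.90), and poglut1 (log2 -1.89), which encodes a glucosyltransferase that modifies Notch. gpm6bb fell by 1.503, osgep by 1.81, pebp1 by 1.62, the centromere protein gene cenph by 1.56 and tubgcp4, of the gamma-tubulin complex, by 1.53 on the log2 scale. By the same rule without the replicate term no gene passed, and the smallest p-values included those of mdm2, bmb, prpf3 and lnx1 among higher genes and of hdac10, poglut1, bcl11ab, gpm6bb and ints2 among lower ones.

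Camera with the preset correlation called 9 of the 30 lists without the replicate term, 5 up and 4 down, and 2 kept the call with an estimated correlation, the splicing list among them; the others named here lost it. List medians below come from the fit with the replicate term and camera p-values from the fit without it, unless another fit is named. Cell cycle and DNA replication genes were lower (median fold 0.837, 47 of 54 below 0, adjusted p = 0.000662, and 0.513 as an adjusted p with an estimated correlation), and of them top2a, the mitotic topoisomerase gene, fell (log2 -0.96, SE 0.121), while the mitotic kinase gene cdk1 stood at -0.58 (adjusted p = 0.0966). Neural progenitor and glial genes were lower (median fold 0.888, 25 of 35 below 0, adjusted p = 0.00486, and 0.262 as an adjusted p with an estimated correlation). Of these hes6 fell (log2 -1.03, SE 0.135), and the Notch targets her15.1 and her4.2 stood at a log2 of -0.98 and -1.43 (adjusted p = 0.0583 and 0.0668). Erythroid genes were lower (median fold 0.843, adjusted p = 0.0393, and 0.899 with an estimated correlation, again an adjusted p), with znfl2a falling by 1.06 and the globin genes hbbe2 and hbae3 at -1.69 and -1.18 on the log2 scale (adjusted p = 0.0875 and 0.0815). The list of mRNA 3' end processing was lower (median fold 0.857, adjusted p = 0.0336, estimated correlation adjusted p = 0.899); its member that fell was ints2 (log2 -1.49, SE 0.147), of the Integrator complex.

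A further 3 lists were higher by camera with the preset correlation. Heat shock genes had a median fold of 1.78 (15 of 16 above 0, adjusted p = 0.00224, with the replicate term 0.047, estimated correlation adjusted p = 0.899), none of which passed alone; with the replicate term the median log2 was -0.216 without mutant replicate 1 and 2.16 without sibling replicate 1. Of them hsp90aa1.1 stood 3.03-fold higher (adjusted p = 0.151). Genes of the notochord and floor plate had a median fold of 1.51 (14 of 17 above 0, adjusted p = 0.00155, estimated correlation adjusted p = 0.262). Their morphogen genes shha and shhb stood at log2 0.90 and 0.76 with adjusted p-values of 0.0998 and 0.145, foxj1a and loxl5b at 1.03 and 0.91 (adjusted p = 0.151 and 0.102), and mdka at 0.15 (adjusted p = 0.551); mdka stood at -0.02 without mutant replicate 2. Ribosome biogenesis genes had a median fold of 1.22 (38 of 48 above 0, adjusted p = 0.0126, estimated correlation adjusted p = 0.899), and of them fbl and nhp2 stood at log2 0.62 and 0.51 (adjusted p = 0.0816 and 0.198). The other 21 lists had median log2 differences from -0.16 to 0.42. Of these, cardiac muscle and pronephros genes were called higher with the replicate term (median fold 1.16 and 1.25, adjusted p = 0.0117 and 0.0173), with adjusted p-values of 0.502 and 0.848 under an estimated correlation. Neither was called against wild-type controls (median log2 -0.046 and 0.297, adjusted p with the term 0.507 and 0.227). Cardiac muscle genes were lower in siblings than in controls (-0.314, adjusted p with the term 0.00759). That difference was not called by camera without the term (adjusted p = 0.0611) or with it under an estimated correlation (0.689). The direction of these 9 called lists was the same under each scaling tried, but not every call held. Of 19 settings without the replicate term and 19 with it, the adjusted p lay under 0.05 in 19 and 18 for cell cycle genes, 17 and 18 for neural progenitors, 17 and 17 for erythroid genes, 12 and 16 for mRNA 3' end processing (largest adjusted p 0.689 without the term), 16 and 17 for ribosome biogenesis (0.842), 18 and 19 for the notochord, and 19 and 12 for heat shock genes (largest 0.743 with the term). Over the settings without the term the median log2 ran from -0.339 to -0.181 for cell cycle genes, -0.374 to -0.172 for neural progenitors, -0.613 to -0.037 for erythroid genes (with the term -0.423 to -0.019), -0.399 to 0.025 for mRNA 3' end processing, 0.055 to 0.531 for ribosome biogenesis, 0.207 to 0.601 for the notochord and 0.44 to 1.035 for heat shock genes. Of the lists that were not called, single members fell: the lysozyme gene lyz of myeloid cells (log2 -1.11), the retinal transcription factor genes atoh7 (log2 -2.55) and rx2 (log2 -1.82), and ednrb1a, an endothelin receptor gene of the neural crest (log2 -2.70). Without the replicate term atoh7 stood at -2.688 (adjusted p = 1), and at values from -5.213 to 0.15 when single libraries were left out; with the term these ran from -2.653 to -2.406 and were not past the threshold without any 1 of the sibling or mutant libraries. With the term, neither atoh7 nor rx2 passed under limma on log2(RPKM + 1), with a pseudocount of 5 or after quantile normalization, and atoh7 stood at -1.049, -0.392 and -0.98 (adjusted p = 0.117, 0.253 and 0.252). The cardiac myosin gene myl7 stood at log2 0.76 (adjusted p = 0.0583). The neutrophil gene mpx, with 2 records, stood at -0.81 by its record with most reads (adjusted p = 0.163). Its other record stood at 0.13 in the fit that kept all records. The retina and lens list had a median log2 of -0.64 in replicate 1 and 1.05 in replicate 2.

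**Figure D3:**
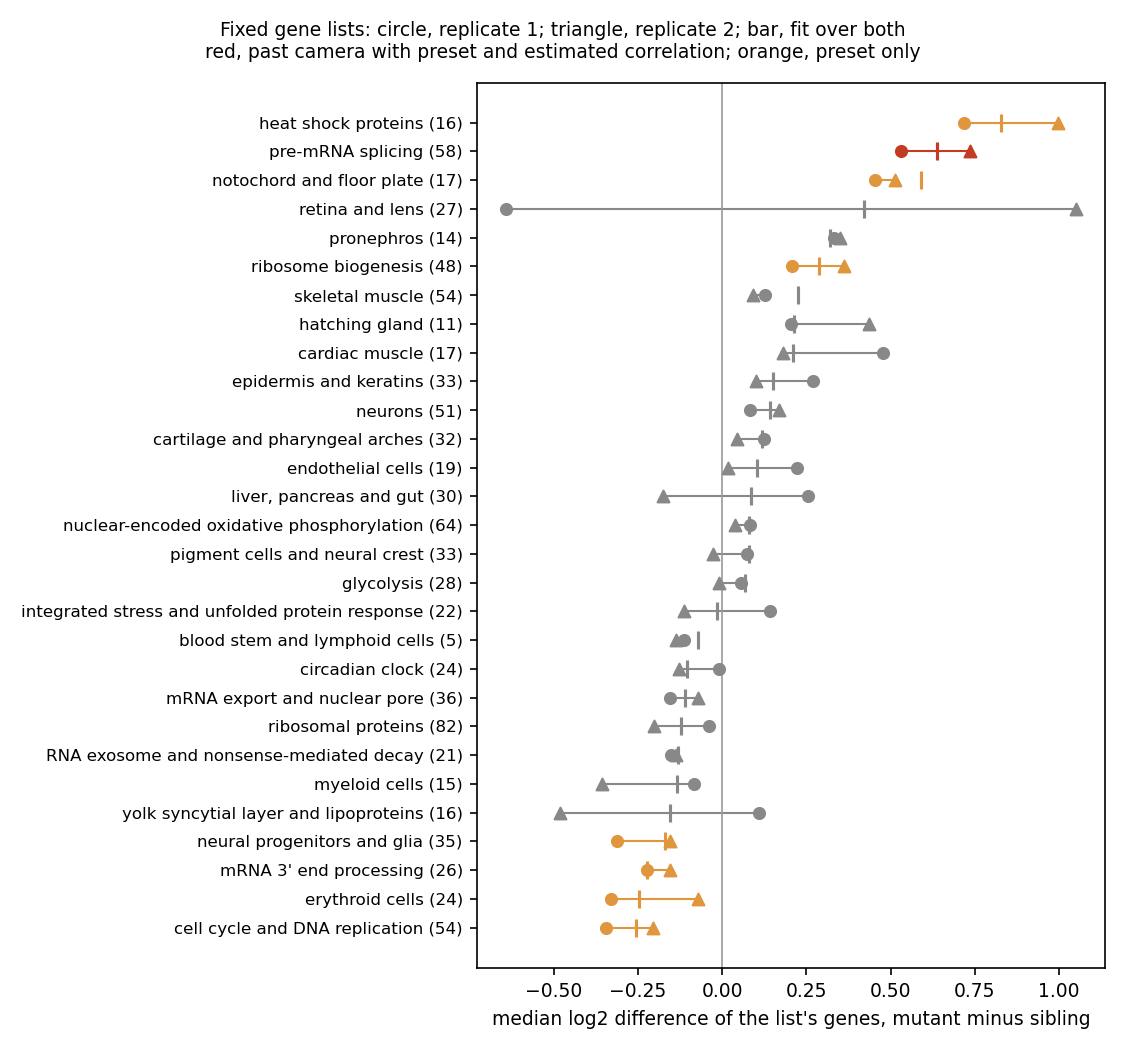
Median log2 difference between mutants and siblings over the tested genes of each gene list reported (x axis), with the number of tested genes in parentheses; circles are replicate 1, triangles replicate 2 and vertical bars the fit over both. The splicing list (0.53 and 0.74), in red, passed camera with both the preset and an estimated correlation in the fit without the replicate term; with the term its adjusted p under an estimated correlation was 0.502. Colours show the fit without the term and bars the fit with it.

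With the replicate term 177 of 10147 tested genes differed between mutants and siblings, 118 higher and 59 lower. Each moved the same way in both replicates, as did 76.7% of all tested genes, but passing this fit favours such genes. Without the term edgeR called 0 genes (534 at an unadjusted p under 0.05, smallest adjusted p 0.0811) and DESeq2 149. Under the authors' totals as library sizes 126 genes were higher and 132 lower, a share higher of 48.8% against 66.7%, and among the 1198 genes DESeq2 called with the term the share was 51.5%. These counts depended on single libraries: 0 genes were called without sibling replicate 1, sibling replicate 2 or mutant replicate 2, 58 without mutant replicate 1, 2235 without control replicate 1 and 2024 without control replicate 2.

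Mutants were next compared with wild-type controls, embryos of unrelated crosses. Of the splicing list 24 genes rose while eftud2 fell (median fold 1.61). Adjusted over the list alone, 35 were higher and 3 lower. prpf3 rose 6.46-fold and gadd45aa 12.1-fold. Among the largest rises, brf2 rose 17.3-fold (0.881 ± 0.598 to 14.2 ± 5.30 RPKM, SD, n = 2), snapc4, a subunit of the snRNA-activating complex, 12.8-fold, and mettl16, the methyltransferase of U6 snRNA, 11.5-fold. ecd rose 7.53-fold. The transcription factor genes sox12, pou3f1 and znf710a fell by 2.41, 1.74 and 1.61 on the log2 scale.

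Against wild-type controls 5 neural progenitor genes fell, among them ascl1a (log2 -0.98) and sox3 (log2 -1.10), with the list lower by camera (median fold 0.843, adjusted p = 8.67e-05, estimated correlation adjusted p = 0.148). The neuronal differentiation gene neurod4 fell (log2 -1.25). Of the cell cycle list mki67 (log2 -0.88), aurkb (log2 -0.78) and top2a fell, and the list was lower (median fold 0.887, adjusted p = 0.0443, estimated correlation adjusted p = 0.97). Ribosome biogenesis (median fold 1.39, adjusted p = 1.13e-06) and oxidative phosphorylation genes (median fold 1.23, adjusted p = 0.00198) were higher, both with an adjusted p of 0.97 under an estimated correlation; they passed in 17 and 16 of 18 settings without the term, and the median log2 of oxidative phosphorylation genes was 0.019 without control replicate 1 (adjusted p = 0.809). Skeletal muscle genes were called higher with the term only (median log2 0.267, adjusted p = 0.00152, without the term 0.0673, and 0.77 with the term under an estimated correlation), in all 18 settings with it, and klhl31 and smyhc1 of them rose. Of the lists called against siblings, the notochord (median log2 0.236, adjusted p = 0.286), erythroid (-0.15, adjusted p = 0.291) and mRNA 3' end processing genes (-0.101, adjusted p = 0.0904) were not called against wild-type controls. Stress and unfolded protein response genes were lower (median fold 0.725, adjusted p = 0.0038, with the replicate term 0.017, and 0.97 under an estimated correlation), with a median log2 of -0.135 in replicate 1 and -0.686 in replicate 2; without control replicate 2 the adjusted p was 0.64 (with the term 0.377). Heat shock genes passed camera without the replicate term (adjusted p = 0.00762) and not with it (adjusted p = 0.159; under 0.05 in 3 of 18 settings). Their median log2 was -1.685 without the term and -1.402 with it, 0.58 in replicate 1 and -2.74 in replicate 2, and without control replicate 2 the list was higher in mutants (0.716, with the term 0.79). Cell cycle genes passed in 10 of 18 settings without the term and 13 of 18 with it. For the splicing list the adjusted p under an estimated correlation was 0.0749, so that no list of this comparison kept its camera call under it. By fry the splicing list had an adjusted p of 0.0149 without the term and 0.0472 with it. Fry called 2 lists of this comparison without the term and 3 with it.

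With the replicate term 353 genes differed between mutants and wild-type controls, 194 higher and 159 lower; without it edgeR called 0 (667 at an unadjusted p under 0.05, smallest adjusted p 0.14) and DESeq2 194. Leaving out 1 library at a time gave 0 without mutant replicate 2, 96 without mutant replicate 1, 58 and 55 without sibling replicate 1 or 2, and 2370 and 1588 without control replicate 1 or 2. Both mutant comparisons called 151 genes in the same direction, 106 higher and 45 lower. All 6 libraries were also simulated with no gene changed, the simulated mutant libraries being shared by both comparisons. This gave a mean of 0.66 such genes over 50 runs, with a maximum of 3, and independent lists of the observed sizes would share 3.18. With no gene changed few calls are expected in either comparison, so the simulation does not say how much of the 151 comes from the shared libraries. The 151 became 0 without sibling replicate 1, sibling replicate 2 or mutant replicate 2, 57 without mutant replicate 1, and 1161 and 962 without control replicate 1 or 2. The covariance of the fold changes across genes was 0.207, against 0.0409 in the simulation. With 2 mutant libraries these could not be divided between the comparisons, so part of the overlap may come from the shared libraries.

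Siblings and wild-type controls, the 2 reference groups, differed for 0 genes by edgeR with or without the replicate term (878 and 100 at an unadjusted p under 0.05, smallest adjusted p 0.564 and 1), while DESeq2 called 12 genes without the term and 98 with it. With the term, edgeR called 415 genes without control replicate 1 and 85 without control replicate 2, and 0 without any other library. The smallest p-values among genes lower in siblings, none past the threshold, were those of fos (1.17 against 13.3 RPKM), atf3 (1.34 against 8.39), junba (0.953 against 5.47), acvr2b (2.32 against 4.34) and ppp1r15a (6.96 against 22.9), of which fos, atf3 and junba encode immediate early transcription factors. Among genes higher in siblings they were those of brf2 (2.12 against 0.881 RPKM), mettl16 (4.29 against 1.76), ccl-c25v (1.96 against 0.0227), lonrf1l (6.72 against 3.11) and rnf113a (12.3 against 7.02).

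Heat shock genes made the largest list difference between the reference groups, and it lay in 1 library. In wild-type control replicate 2 the list took 5.69% of reads (95% Wilson interval 5.68 to 5.70, counting error only), against 0.482% to 1.16% in the other 5 libraries, and hsp70l stood at 1642 RPKM there and at 4.54 in control replicate 1. The list's median log2 difference, siblings minus controls, was -0.28 in replicate 1 and -3.84 in replicate 2 (camera adjusted p = 9.8e-19, estimated correlation adjusted p = 0.514). Camera called 9 lists, and with an estimated correlation 0. Higher in siblings were splicing (median fold 1.14), ribosome biogenesis (1.15), skeletal muscle (median log2 0.27) and oxidative phosphorylation genes (1.15). Lower were stress and unfolded protein response (0.793), neuronal (0.85), neural progenitor (0.914), heat shock (0.187) and notochord genes; the last had a median fold of 1.01 with a mean log2 of -0.23, so that median and test differed in sign. The stress list had a median log2 of -0.052 in replicate 1 and -0.695 in replicate 2 and was not past the threshold without control replicate 2 (adjusted p = 0.738, with the replicate term 0.147). Neural progenitor and notochord genes passed in 11 of 18 settings each without the term, and in 16 and 9 with it. Splicing, ribosome biogenesis, skeletal muscle, oxidative phosphorylation and neuronal genes passed in 16 of 18 each without the term. In that fit the medians of ribosome biogenesis and skeletal muscle genes were below 0 without sibling replicate 1 (-0.122 and -0.393) or control replicate 2 (-0.119 and -0.214), and that of oxidative phosphorylation genes without control replicate 1 (-0.119) or sibling replicate 2 (-0.05). The lists of mRNA export (higher, adjusted p = 0.0377) and cardiac muscle were called with the term only. Under an estimated correlation their camera adjusted p-values with the term were 0.766 and 0.689.

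**Figure D4:**
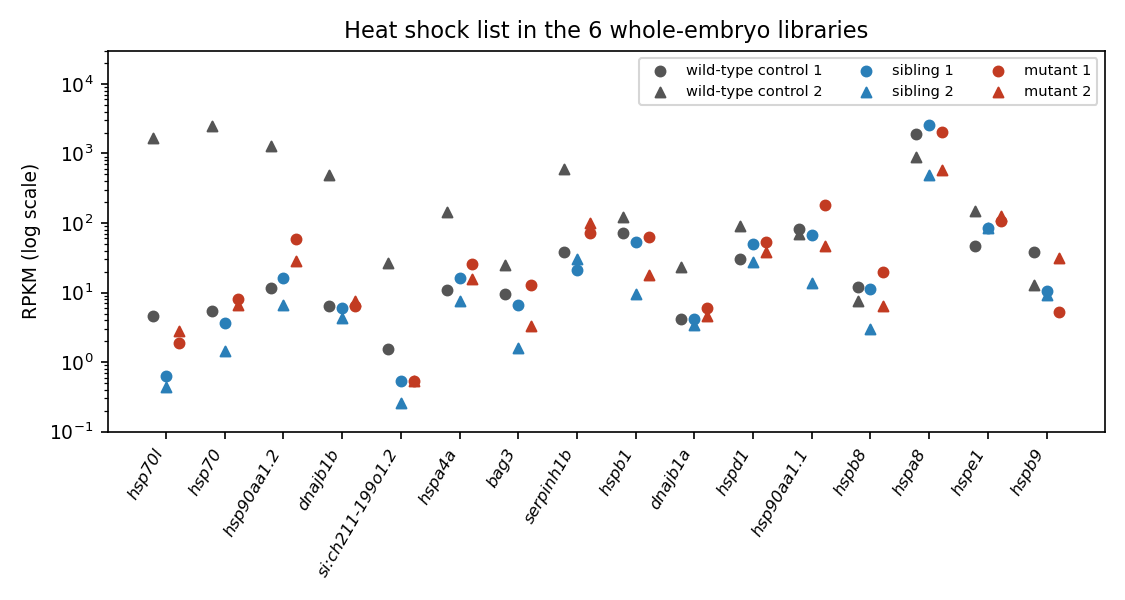
RPKM on a log axis of the 16 tested heat shock genes (x axis) in the 6 whole-embryo libraries; circles are replicate 1 and triangles replicate 2. Wild-type control replicate 2 lies above the other libraries for most genes, with hsp70l at 1642 RPKM against 0.433 to 4.54 elsewhere.

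The nuclear and cytoplasmic libraries address where transcripts of mutants and siblings lie in the cell. With 1 library each there was no test, and differences compare these libraries. In the mutant nuclear library 80.8% of the authors' total lay outside the listed transcripts, against 66.5% in sibling nuclei, 58.3% in sibling cytoplasm and 58.2% in mutant cytoplasm, with 95% Wilson intervals of 80.77 to 80.79 and 66.48 to 66.51 for the nuclear libraries that cover counting error only. RPKM divides by that total. The median log2 ratio of nucleus to cytoplasm over 8631 genes was -0.22 in siblings and -1.06 in mutants, and the median of the gene-by-gene difference was -0.79 as deposited; after each library was rescaled it was 0.05 by construction. Values below are relative to the median gene.

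Transcripts that rose in whole mutant embryos were also higher in both fractions. Of 117 such genes measured, 108 were above the median gene in mutant nuclei (median log2 1.33) and 117 in mutant cytoplasm (median 1.28); of 52 that fell, 48 were below it in nuclei (median -0.71) and 52 in cytoplasm (median -1.11). Across genes, the whole-embryo fold change correlated with that of the cytoplasm at r = 0.823 and of the nucleus at r = 0.36, and genes are not independent replicates. The splicing genes had a median of 0.51 in the nucleus and 0.53 in the cytoplasm, and both medians lay at the top of 10000 random lists matched on expression.

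**Figure D5:**
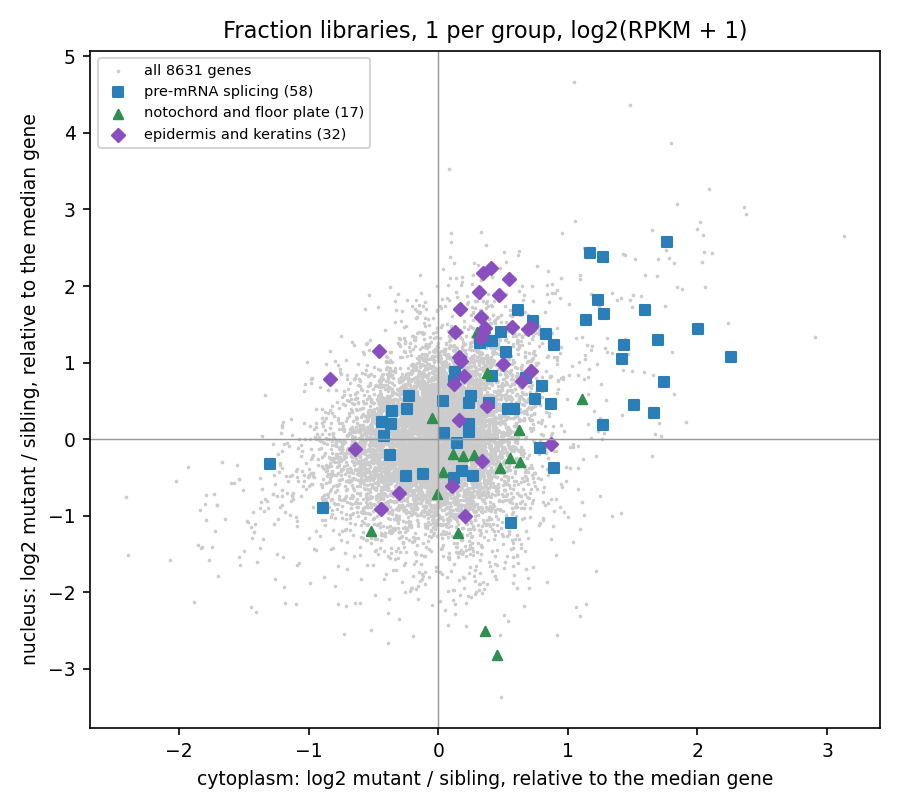
Log2 ratio of mutant to sibling in the cytoplasm (x axis) and nucleus (y axis) for 8631 genes, each relative to the median gene, from 1 library per group; colours mark 3 gene lists. The medians of the splicing genes (0.53 and 0.51) lie above 0 in both fractions.

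The balance between the fractions shifted for some groups. The largest relative gains of the mutant nucleus were those of rn7sk, the 7SK small nuclear RNA, with 30 reads in sibling and 537 in mutant nuclei (difference of the log2 ratios 3.56; whole-embryo log2 1.24, adjusted p = 0.454, and -0.02 without sibling replicate 1), nfkbiaa (3.38), fos (2.82), tnks1bp1 (2.23), pho (2.22), onecut1 (2.2), arid4a (2.13), rbbp6 (2.12), twistnb (2.12) and hbegfa (2.101). The largest relative losses included genes of the extracellular matrix: hapln1a, a link protein gene of cartilage (-3.91), the collagen genes col2a1a (-3.35), col11a2 (-3.10) and col8a1a (-2.94), and fstl1b (-3.54). By counts not scaled for depth, the type II collagen gene col2a1a had 52892 reads in sibling nuclei and 3525 in mutant nuclei, but 27792 in sibling and 41900 in mutant cytoplasm. The others were rtn2a (-3.36), sgcb (-3.32), bag3 (-3.00), bag2 (-2.98) and plp2 (-2.91). sgcb and bag2 have 2 placements in the files.

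Among the lists, notochord and floor plate genes had a lower nucleus to cytoplasm ratio in mutants than in siblings (median difference -0.65, percentile 0.06 of matched random lists, 14 of 17 below 0). Cartilage and pharyngeal arch (-0.63, percentile 0), skeletal muscle (-0.27, percentile 0.01) and heat shock genes (-0.46, percentile 0.25) had medians below 0, but their members went both ways, with 18 of 29, 31 of 53 and 9 of 16 below 0. Epidermal and keratin genes (0.73), genes of liver, pancreas and gut (0.70) and oxidative phosphorylation genes (0.55) had a higher ratio in mutants, each at percentile 100. Whether transcripts of any of these lists moved within cells was not tested. In siblings heat shock, skeletal muscle and notochord genes were the 3 most nuclear lists (median log2 ratio of nucleus to cytoplasm 1.824, 0.714 and 0.602), and yolk, erythroid, liver, pancreas and gut and epidermal genes the 4 most cytoplasmic (-2.585, -1.629, -1.431 and -1.353). In mutants these medians were 1.033, 0.663 and 0.009, and -2.031, -1.931, -0.948 and -0.779. By these medians 6 of the 7 lists lay nearer the median gene and the erythroid list further from it. Gene by gene, however, the erythroid list had a median difference of 0.401, with 15 of 21 above 0. Most of its members thus had a higher ratio in mutants, relative to the median gene. Lists picked as the extremes of the sibling ratio tend to lie nearer the median in any other pair of libraries. Over the pseudocounts, filters and scalings tried, the median ran from -1.29 to -0.28 for cartilage, -1.22 to -0.646 for the notochord, -0.555 to -0.0148 for skeletal muscle, -0.759 to -0.179 for heat shock, 0.427 to 1.11 for epidermis, 0.466 to 1.05 for liver, pancreas and gut and 0.248 to 0.841 for oxidative phosphorylation. ccng1 had 21944 reads in sibling and 6423 in mutant nuclei and 11369 and 29751 in the cytoplasm. These counts are not scaled for depth: the listed reads were 14141991 in sibling and 7164408 in mutant nuclei, and 17696776 and 19195327 in the cytoplasm. The median of the splicing genes was 0.04 (percentile 34.9; -0.258 to 0.312 over the settings tried).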

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

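The tests of RNA carried over from the cytoplasm were chosen after the result was seen; the other test in this part was set out before. Reads outside the listed transcripts made up 80.78% of the authors' total in the mutant nuclear library, above the 66.49% of its control, the sibling nuclear library, while the cytoplasmic libraries stood at 58.15% and 58.3%. What those reads are was not analysed here. The part played by low counts in this library of 7164408 listed reads was not settled. The most abundant 10% of genes also had a median log2 change of -0.656 in the mutant nucleus as deposited, against -0.837 over all genes. But RPKM divides by the authors' total, of which 33.51% lay on listed transcripts in sibling nuclei and 19.22% in mutant nuclei. That lowers genes of every abundance, so this test was largely fixed in advance and does not decide. Cytoplasmic RNA carried into the mutant nuclear library does not account for the high share: with 58.15% of its reads outside the listed transcripts, it could only lower the share of a nuclear library that stands at 80.78%. It would also draw the 2 profiles together. Over the more abundant genes the interquartile range of the log2 ratio was 1.95 times that of siblings (0.939 against 0.481). Other differences of the mutant nuclear library, such as its fewer reads, can widen this range, so it does not decide. An earlier form of the test ranked genes on the same library and was void, and so was a condition on yolk genes, picked as the most cytoplasmic list of the sibling libraries that enter the difference. The yolk genes had a median difference of 0.546, with 16 of 16 above 0, the direction that carry-over would give. Some carry-over beside another source of the high share was therefore not excluded. The comparison of shares was added after the results of the earlier tests had been seen. Whether the mutant fractions were separated less completely was not tested otherwise. Other sources such as unspliced RNA, ribosomal RNA or DNA, and a biological effect of the mutation, stay open and untested in a single library.

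For 3 genes among those with the largest shifts between fractions, the mutant effect had opposite signs in nucleus and cytoplasm, with at least a 2-fold change in each. The difference between the effects in nucleus and cytoplasm was -3.362 (log2) for rtn2a, -3.315 for sgcb and -3.001 for bag3. With 1 library per group the difference was not tested. The mutant nuclear library held 35, 10 and 157 reads of these genes.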

How the results depend on the processing

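Alternatives that use DESeq2, the authors' totals or all records, and all that combine the replicate block with another choice, were chosen after seeing the data. Replicate numbers were given by the labels, and no label says what they mark. Deviations from the group means of same-numbered libraries correlated at 0.758, 0.714 and 0.866 across genes; with 2 numbers this is a hint and not evidence of pairing, but the number also marks a processing batch. With the replicate block the counts of genes moved from 0 to 177 (mutant against sibling), from 0 to 353 (mutant against wild-type control) and from 0 to 151 (both), and stayed at 0 for sibling against control. Without the block, quantile normalization gave 1, 3 and 1 genes, and DESeq2 gave 149, 194, 117 and 12 (the last for sibling against control); the counts of lists past camera, 9, fell to 2 with an estimated correlation and 2 with fry, and ranged from 9 to 14 when a library was left out. All other alternatives without the block left these counts of genes at 0, including every fit without a library, and apart from those fits left lists between 8 and 11. The cause of these differences was not tested.

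With the replicate block, mutant against sibling gave 272 genes with limma, 282 with limma and a pseudocount of 0.1, 115 without an abundance trend, 1198 with DESeq2 and 2251 with only the 4 libraries compared. Mutant against wild-type control gave 215 without a trend, 1721 with DESeq2 and 49 with only the 4 libraries. DESeq2 gave 98 genes for sibling against control and 856 in both mutant comparisons. For mutant against sibling, mutant against control and both, leaving out control replicate 1 gave 2235, 2370 and 1161, control replicate 2 gave 2024, 1588 and 962, sibling replicate 1 gave 0, 58 and 0, sibling replicate 2 gave 0, 55 and 0, mutant replicate 1 gave 58, 96 and 57, and mutant replicate 2 gave 0 in each. Sibling against control gave 415 and 85 without control replicate 1 or 2 and 0 without any other. The cause was not tested. A group left with 1 library is assumed to vary like the others, and 1 residual degree of freedom remains. When 1 control library is left out, the other is fitted exactly, so the spread comes from siblings and mutants alone, as with only those 4 libraries. The differences within replicate 1 and within replicate 2 correlated across genes at 0.735 for mutants against siblings. For mutants and siblings against controls they correlated at 0.421 and 0.106. Lists moved from 11 to 0 with an estimated correlation and to 4 with fry. Of the single-gene values under these alternatives, 231 lost the threshold, 91 gained it and 3 reversed. Without the block 51 gained it and 6 reversed. With all records, a gene with several was read from the first listed, so the reversals of mpx in both counts are values of its other record.

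The fraction difference of -0.794 became -1.09 with a pseudocount of 0.1, -0.805 at a mean RPKM of 5 or more and -0.492 without a filter. It reversed to 0.053 after rescaling and 0.0444 after quantile normalization, which set the medians of the libraries level. Without the block, eftud2 in siblings against controls reversed to 0.178 without control replicate 1 and 0.073 without sibling replicate 2 (lowest -0.425). In mutants against siblings, atoh7, which was past the threshold with the block only, reversed to 0.15 without sibling replicate 2 (lowest -5.213). With the block it ran from -2.653 to -2.406 when single libraries were left out. rn7sk reversed to -0.011 (with the block -0.017) without sibling replicate 1 (highest 3.263). mdka reversed to -0.054 (with the block -0.016) without mutant replicate 2 (highest 0.34). For mpx the value with all records, 0.133 (with the block 0.131), is that of its other record and not a change of the same record. None of these genes was past the threshold in the fit where its sign differed, and the cause was not tested for atoh7, rn7sk and mdka. The fraction libraries are limited by having 1 library per group and by depth, with 7164408 listed reads in mutant nuclei. In whole embryos, with 2 libraries per group, a 2-fold change was recovered in 46% of simulated genes with the block.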

Other observations

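The tests of muscle genes, of heat shock copies, of other stress genes and of the sibling shift were chosen after the results were seen; those of transcript length, intronless genes and snRNP genes were written before their results, except for the match on transcript length. In the sibling fractions, gene lists took distinct places. Genes of the yolk syncytial layer had the lowest nucleus to cytoplasm ratio (median log2 -2.59 relative to the median gene, 16 of 16 below 0), followed by erythroid (-1.63), liver, pancreas and gut (-1.43) and epidermal genes (-1.35). Heat shock genes (1.82, 16 of 16 above 0), skeletal muscle genes (0.71, 53 of 53) and notochord genes (0.60) stood highest. These describe 1 library per fraction.

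The libraries of the 2 replicate numbers differed for 4783 genes by edgeR, 2443 higher and 2340 lower in replicate 2. Longer transcripts were lower in replicate 2: the median log2 difference was 0.23 for transcripts of up to 1319 bases and -0.27 for those of 2599 or more. The correlation with length across genes was -0.275 (Spearman), short of the size of 0.3 set for it. That size was a choice and the value lies near it, so it does not decide how much of the difference goes with length. Skeletal muscle genes stayed lower after a length trend was removed (median -0.837, matched random lists -0.158 to 0.26), and 45 of 54 were lower in replicate 2 before that correction. Endothelial genes (-0.74) were also lower and erythroid (0.74) and pigment cell genes (0.55) higher in replicate 2, so a difference in the embryos collected may add to one in library preparation; the design gives no group that would test it.

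Wild-type control replicate 2 carried high heat shock transcripts. Reads shared between near-identical copies do not account for it, since the 15 genes with 1 record and 1 placement had a median log2 excess of 3.26 over the other replicate 2 libraries, 14 of them above 0. The integrated stress and unfolded protein list was also in excess (median 0.729, 18 of 22 above 0, matched random lists -0.198 to 0.148), which is consistent with a stress response in those embryos. Whether heat or handling set it off was not tested. It bears directly on comparisons with the wild-type controls. The comparison between mutants and siblings can be touched through the shared estimate of spread and, where fitted, through the replicate term that all 3 groups share.

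A hypothesis was that siblings, which include heterozygotes, show part of the mutant response. The 118 genes that rose in mutants against siblings had a median log2 difference of 0.177 between siblings and wild-type controls (82 above 0, matched random sets -0.0367 to 0.0602), 0.11 in replicate 1 and 0.17 in replicate 2. Their median in mutants against siblings was 1.52. Selection for low sibling values would push this measure below 0, so the shift may reflect heterozygotes, mutant embryos among the siblings or the background of the crosses, which these data do not separate. The 59 genes that fell had a median of 0.09.

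A further hypothesis was that genes for snRNA synthesis and snRNP assembly rise in mutants beyond brf2, snapc4 and mettl16. A list of 38 other such genes did not: the median log2 was -0.0193 (19 above 0, matched random lists -0.169 to 0.141), with sart3 and ppie called higher. Intronless protein-coding genes did not stand apart in whole embryos either (median -0.0458 over 208 genes, random sets -0.0665 to 0.0522). In the mutant nucleus the 174 intronless genes had a median of 0.103 relative to all genes, above random sets matched on expression (up to 0.093) which is what the test had asked for. A second match, on transcript length too, was added after that result, and by it the value was not above random sets (up to 0.122). Among genes with introns, the nuclear change went from 0.18 in the lowest of 4 equal groups by intron length to -0.15 in the highest (Spearman rho -0.183 across 8445 genes, -0.142 given transcript length), so a link between intron content and the mutant nuclear library may exist but rests on 1 library.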
